A study of Arabidopsis thaliana with 36 samples.

How the data were processed

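Apical regions of Arabidopsis thaliana were profiled with 36 ATH1 arrays hybridized with biotin-labelled RNA, 1 array per sample. Per the labels, 3 lines were sampled after 0, 3, 5 and 7 long days following short days, which gave 12 groups with 3 replicates each. The deposited values were signal intensity per probe set on a linear scale, made by the authors with MAS5 per the submitters' processing notes. The version of MAS5, its scaling target and any masking are not stated. The 2%-trimmed mean signal lay between 100.007 and 100.009 on the 36 arrays, so the deposited values were used without further scaling. The median signal per array ran from 40.4 to 43.1. The number of arrays limits the precision.

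Each signal was transformed as log2 of the signal plus an offset of 1.62, the 10th percentile of all values. Of 22810 probe sets, 64 control probe sets were left out. A probe set was tested where its signal exceeded the array's own 40th percentile on at least 3 of the 36 arrays, which left 14912 probe sets. The 40th percentile lay between 19.8 and 24.8 on the arrays. The size of a log2 difference depends on the offset where a group compared has a dim mean, below the average of these percentiles. Of 108 named values 85 had such a group. At an offset of 16, 41 of these were smaller by over 1.5 times, and 106 of the 108 kept their call. The fit used limma 3.58.1 in R 4.3.3 with 1 mean per group and 24 residual degrees of freedom, and eBayes with an intensity trend. All tests were two-sided unless named otherwise, and p-values were adjusted by the Benjamini-Hochberg method over the 14912 probe sets of a comparison. A probe set was called at an adjusted p under 0.05. The p-values measure the spread between these samples only, and the labels do not state whether replicates came from separate pools of plants.

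The comparison of lines averaged the difference over the 4 days, with 12 arrays against 12. Day responses compared 3 arrays with the 3 day 0 arrays of the same line. Interaction contrasts tested whether the day 7 response differed between lines. These comparisons share arrays: FRI flc-3 enters both line comparisons, and each day 0 group enters all responses of its line. No overlap between comparisons that share arrays was tested.

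Probe sets were named from an annotation table that lists 14016 of them. It gives 1 gene for 13513 probe sets and several genes for 503. Of the former, 13436 matched a locus of the reference annotation and 77 did not. Among the tested probe sets 8041 named loci remained, with the probe set of highest mean signal taken for each locus. The table leaves 8730 probe sets that are not controls without a name, and such probe sets are given by their identifier. FLC, FRI and SOC1 are not named in this table and are not reported by name, and the unnamed probe sets given here were not matched to genes.

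Named genes followed a rule. For the line comparisons it took the 10 called loci of largest change in each direction whose difference had the same sign on all 4 days. For each day 7 response it took the 8 called loci of largest change in each direction whose arrays did not overlap between the days. For each difference between responses it took the 5 called loci of largest change in each direction. Of each gene list described, it took up to 4 members of smallest adjusted p. At most 2 unnamed probe sets are given per direction. Design, groups, tests, this rule, 15 gene lists and most alternatives were fixed before the data were examined.

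Of the 15 lists, 8 had at least 2 tested members, 4 had 1 and 3 had none. Most members fixed for a list were not tested. Tested were 3 of 16 floral integrators and promoters, 3 of 12 flavonoid and anthocyanin genes and 3 of 12 cold and dehydration genes. Likewise 4 of 28 photosynthetic leaf genes, 3 of 32 cell cycle genes and 3 of 26 gibberellin genes were tested. A list result thus speaks for its tested members only. The lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 104 tests. The lists of vascular tissue markers, salicylate defence and heat shock had no tested member. A pair of further lists (low oxygen, aliphatic glucosinolates) and families of shared symbol were chosen after values had been seen. A window at the top of chromosome 4, from AT4G00005 to AT4G03000, was tested with Fisher's exact test, with 95% confidence limits for the odds ratio.

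Alternatives were other offsets, quantile normalization, scaling to the 75th percentile, no filter, a filter at the 60th percentile, a replicate block, array weights, eBayes without the trend, a fit to only the arrays compared, and leaving out each array in turn. An offset of 16 was added after the data had been seen. The procedure was tested on simulated data with independent normal noise and no repeat runs. Of 14912 probe sets, 67 were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold, far fewer than were called in the data. In the simulation, 92.5% of probe sets changed 1.5-fold were recovered for 12 arrays against 12, 68.7% for a day response and 49.3% for a difference between responses. For 4-fold changes these shares were 100%, 100% and 98.5%. False calls made up 7.58%, 4.86% and 6.67% of all calls. These rates need not hold where more probe sets change or where probe sets vary together.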

Results

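Signals were measured in the apical region of soil-grown plants of 3 lines, with 12 arrays each. FRI carries the FRI allele of accession Sf-2 in a Col background with a functional FLC, FRI flc-3 carries the same FRI allele with a mutant FLC, and flc-3 has the mutant FLC without that FRI allele. FRI encodes an activator of the floral repressor FLC, and flc-3 is a fast-neutron allele. Each line had 3 arrays at each of 0, 3, 5 and 7 long days. The labels give the stage as vegetative for all FRI arrays, and as transition for FRI flc-3 from day 3 on. For flc-3 they give transition at days 3 and 5 and for 1 of the 3 arrays of day 7.

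The first principal component took 45.5% of the variance and the next 12.8%. The lowest correlation within a group was 0.979, in FRI flc-3 at day 0, where replicate 3 stood apart. The lowest between any pair of arrays was 0.900.

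**Figure D1:**
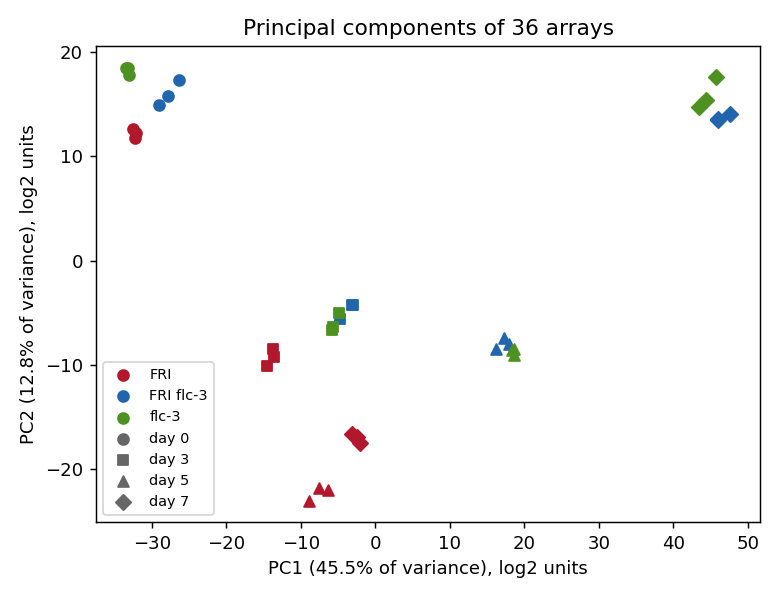
Scores of the 36 arrays on the first 2 principal components of the log2 signals, in log2 units, with colours for lines and marker shapes for days. On the first component, which took 45.5% of the variance, FRI at day 7 scored from -3.21 to -2.03, and FRI flc-3 at day 3 from -4.82 to -3.05. On the second they stood apart, from -17.6 to -16.7 and from -5.61 to -4.26.

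The comparison of FRI with FRI flc-3 asked what changed with a functional FLC in plants that share the FRI allele. As means over the 4 days, the few tested genes of floral promotion were lower in FRI and those of anthocyanin synthesis were higher. At day 0 AGL42 had 12.8 in FRI and 14.8 in FRI flc-3, and FD had 26.9 and 31.8. PYK10, a beta-glucosidase of endoplasmic reticulum bodies, had a log2 difference of 1.94 ± 0.05 (SE, 12 against 12 arrays), with mean signals of 616.3 and 262.3. WSD1, a wax ester synthase, was lower in FRI by a log2 difference of -2.21 ± 0.12, with 9.32 against 88.8. In FRI flc-3 its signal rose from 13.7 at day 0 to 267.5 at day 7. A mean over the days thus need not stand for a steady difference. Of 14912 probe sets, 3160 were called, 1658 higher and 1502 lower in FRI, and 150 of them differed at least 2-fold.

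Other loci higher in FRI on each of the 4 days were AT3G45160 at 1.85, scpl31 at 1.83, AT1G49310 at 1.59, AT1G19960 at 1.53 and AT5G61660 at 1.46, all as log2 differences. The jacalin-related lectins JAL22 and JAL33 were higher by 1.56 ± 0.07 and 1.40 ± 0.09, and AT3G57010 and AT3G28540 by 1.36 ± 0.16 and 1.34 ± 0.21. Lower in FRI were AT5G24240 at -4.19 ± 0.16, with 1.92 against 63.1, and AT1G02190 at -1.96. In flc-3, whose FLC is also mutant, AT5G24240 had a signal of 2.60, so this locus did not follow FLC. UGT84A1, a glucosyltransferase of hydroxycinnamates, stood at -1.85 and the cytochrome P450 CYP71B22 at -1.41. AT1G54020 and AT3G28500 were lower by differences of -1.77 and -1.52, with signals of 47.0 against 259.3 and 189.4 against 746.4. AT4G14980, AT3G12470 and AT5G15780 followed at -1.50, -1.40 and -1.32. Adjusted p for these 20 loci ran from 5.2e-27 to 3.1e-04. Of the 20, 10 had a dim mean over the days in 1 line, such as UGT84A1 with 2.96 against 21.0 and AT1G02190 with 6.45 against 40.4. At an offset of 16 all 10 kept their call with differences smaller by over 1.5 times, AT5G24240 at -2.13, UGT84A1 at -0.79 and AT1G02190 at -1.07. Of the unnamed probe sets, 250476_at was higher in FRI by 4.23 ± 0.06, with 782.7 against 41.7, and 260037_at by 2.14. The probe sets 247553_at and 267509_at were lower at -3.28 and -2.96.

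Floral integrators and promoters were lower in FRI in 3 of 3 tested members, adjusted over the list alone also 3. They were AGL42, a MADS-box gene, at -1.09 ± 0.07, FD, the bZIP partner of FT, at -0.75 ± 0.08, and the MADS-box gene AGL24 at -0.20 ± 0.05 (list adjusted p = 5.7e-05). Flavonoid and anthocyanin synthesis was higher in FRI in 3 of 3 members, 3 adjusted over the list alone (list adjusted p = 2.4e-09). DFR, which reduces dihydroflavonols, stood at 1.02 ± 0.04, and the glycosyltransferases UF3GT and AT4G14090 (UGT75C1) at 0.78 and 0.76. Both list calls held with an estimated correlation. UFO, which acts in floral meristems, was lower at -1.17 ± 0.20, and the floral repressor SMZ was higher at 0.84 ± 0.10, each as the only tested member of its list. UFO was dim in all 8 groups, with 2.26 against 8.38, and at an offset of 16 UFO and SMZ stood at -0.38 and 0.45, both called. THI2.1, a thionin induced by jasmonate, was lower at -0.92 ± 0.10. Of the cold and dehydration genes 2 of 3 were higher, COR15A at 0.43 and LTI30 at 0.52 (0.19 and 0.28 at an offset of 16, both called), and the list did not pass (adjusted p = 0.24). The cell cycle list did not pass (adjusted p = 0.13). In it AUR1 was lower at -0.17, and the call of AUR2 ended without any 1 of 4 arrays (adjusted p from 0.055 to 0.061). Gibberellin genes had 1 of 3 members lower, GID1C at -0.33 ± 0.10 and at -0.18 at an offset of 16 (list adjusted p = 0.67), and photosynthetic leaf genes had a median of 0.09 (list adjusted p = 0.28). Of the latter, the call of LHCB4.1 at 0.14 ended in a fit to only the arrays compared (adjusted p = 0.060), with no filter (0.066), with eBayes without the trend (0.058) and without any 1 of 11 arrays, and that of PRK without FRI day 7 replicate 1 (adjusted p = 0.052). GI and AT1G69570 (CDF5) of the circadian list had differences of 0.08 and 0.05 with adjusted p of 0.35 and 0.83. The FLC regulators FY, LD and AT2G30120 (FLX) had differences of -0.01, 0.02 and 0.04 with adjusted p of 0.87, 0.87 and 0.86. LAS of the shoot meristem list had a difference of 0.08 with adjusted p = 0.56.

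**Figure D2:**
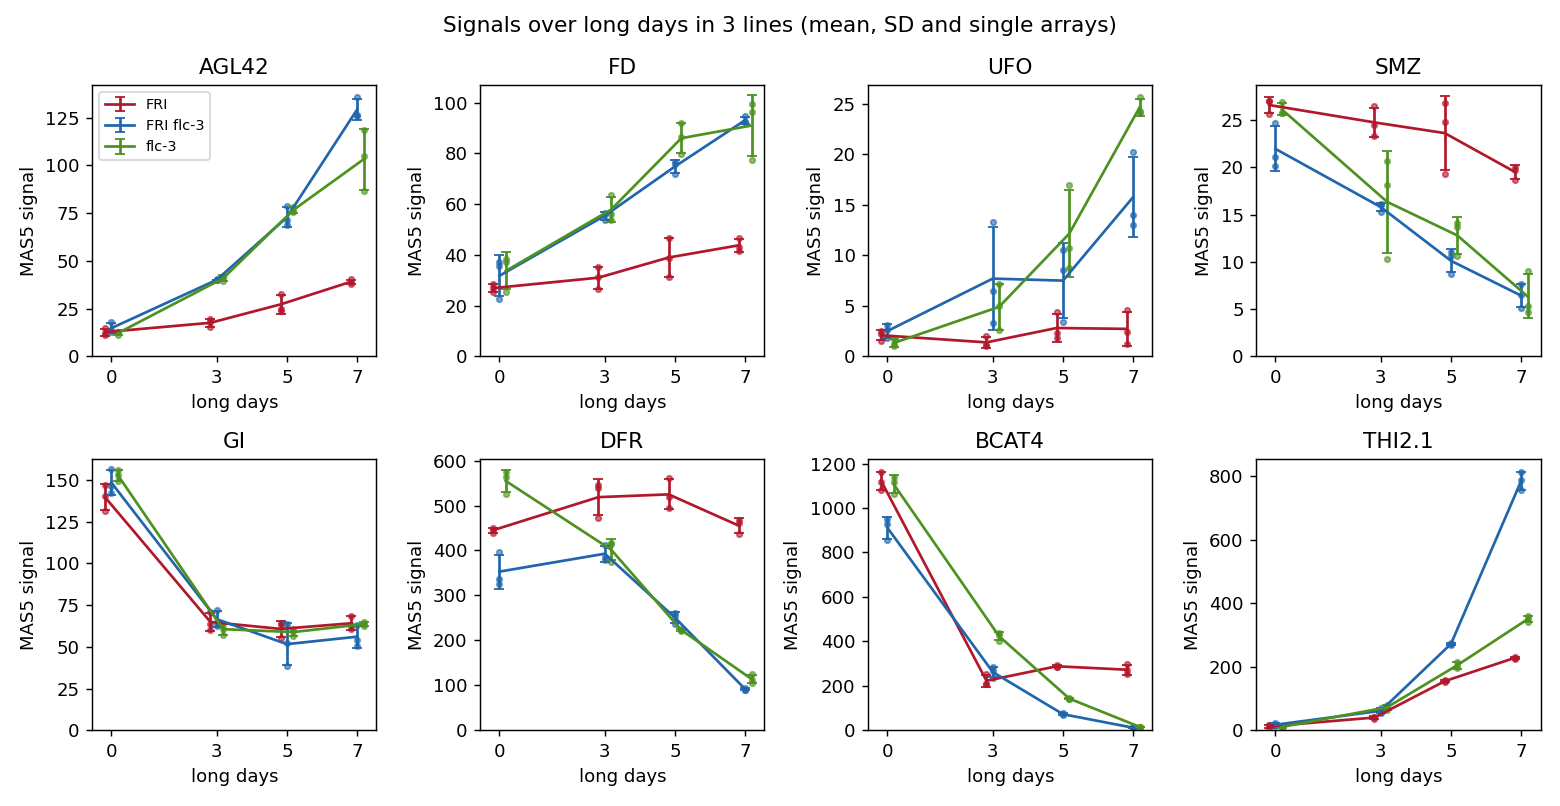
MAS5 signal (linear scale) of 8 genes against the number of long days in FRI, FRI flc-3 and flc-3. Lines join group means, bars are SD and points single arrays (n = 3 per group). AGL42 reached 39.1 in FRI, 129.3 in FRI flc-3 and 103.2 in flc-3 at day 7.

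The comparison of FRI flc-3 with flc-3 asked what the FRI allele changed where FLC was mutant. Fewer probe sets differed, and loci at the top of chromosome 4 were frequent among them. AT4G01910 was lower in FRI flc-3 by a log2 difference of -2.75 ± 0.25 (SE, 12 against 12 arrays), with signals of 2.63 and 23.9, and by -1.10 at an offset of 16. AT5G24240 was higher at 4.03 ± 0.16, with 63.1 against 2.60. FRI, which carries the same allele, had 1.92, so AT5G24240 set FRI flc-3 alone apart and did not follow the allele. There were 632 calls, 290 higher and 342 lower in FRI flc-3, of which 12 differed at least 2-fold. With the arrays scaled to a common 75th percentile there were 675 calls, 381 higher and 294 lower, so the balance of directions depends on the scaling.

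Also higher on each of the 4 days were AT4G01700 at 0.79 ± 0.16, AT5G08600 at 0.73, IAGLU, a glucosyltransferase of indole-3-acetate, at 0.54, AT1G12570 at 0.50, AT4G30450 and AT1G22890 both at 0.48, AT5G55450 at 0.46, AT5G59240 at 0.42 and AT4G17480 at 0.39. Lower were AT4G01410 at -1.21 ± 0.15, AT4G00870 at -1.20, AT4G02360 at -1.12, AT4G00520 at -0.95 ± 0.07, AT4G01460 at -0.87, AT4G01860 at -0.73, AT5G41400 at -0.71, AT2G14650 at -0.63 and AT4G01650 at -0.62. Adjusted p for these loci ran from 1.4e-19 to 0.015. The 20 named loci kept their call at an offset of 16, 8 with differences smaller by over 1.5 times, among them AT5G24240 at 2.08, AT4G00870 at -0.55, AT5G41400 at -0.32 and AT4G01700 at 0.41. The unnamed probe sets 264324_at and 255479_at were higher at 1.72 and 1.60, and 255645_at and 253995_at lower at -3.03 and -1.40.

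In the window at the top of chromosome 4, 30 of 99 tested loci (30.3%) were called, 8 higher and 22 lower in FRI flc-3. Outside it 257 of 7942 were called (3.24%). The odds ratio was 13.0 (95% confidence limits 8.02 and 20.6, Fisher's exact test, p = 1.9e-20). For FRI against FRI flc-3, which share the FRI allele, 15 of 99 loci in the window were called and 1453 of 7942 outside, with an odds ratio of 0.80 and an exact p of 0.51.

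**Figure D3:**
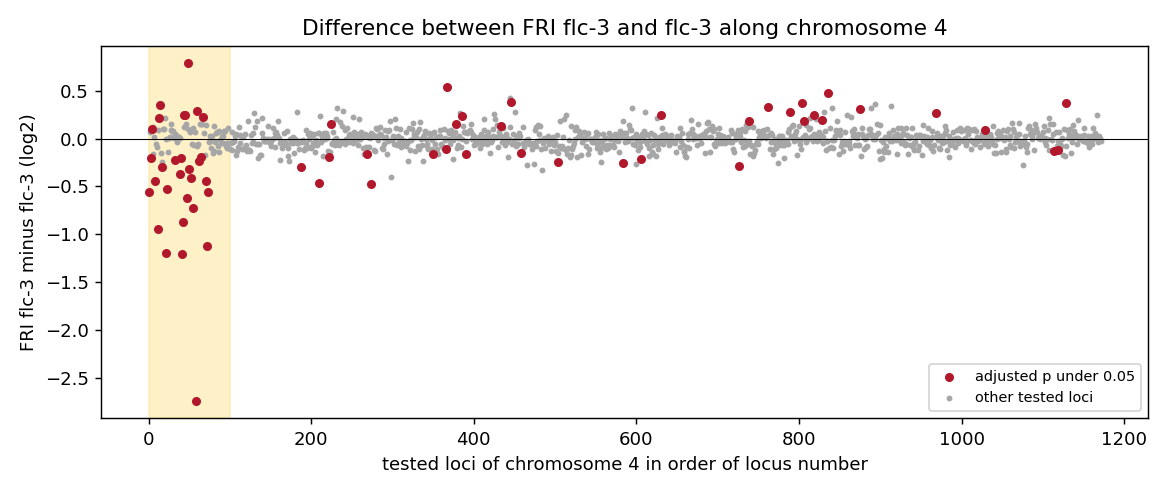
Log2 difference between FRI flc-3 and flc-3 for the tested loci of chromosome 4 in the order of locus number, with called loci in red. The shaded window held 30 calls among 99 loci.

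Flavonoid and anthocyanin synthesis was lower in FRI flc-3 than in flc-3 in 2 of 3 members, and in 3 adjusted over the list alone (list adjusted p = 7.7e-04, which held with an estimated correlation). DFR stood at -0.21 ± 0.04 and UF3GT at -0.21 ± 0.05, and leaving out replicate 1 of FRI flc-3 at day 5 ended the call of UF3GT (adjusted p = 0.052). THI2.1 was higher at 0.50 ± 0.10. The floral integrators AGL42, FD and AGL24 had differences of 0.12, -0.07 and 0.04 with adjusted p of 0.35, 0.66 and 0.73 (list adjusted p = 0.72). UFO and SMZ had differences of -0.09 and -0.12 with adjusted p of 0.88 and 0.59. PRL, the MCM7 helicase subunit of replication licensing, was lower at -0.23 ± 0.05, and the cell cycle list did not pass (adjusted p = 0.21).

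The responses to long days asked which transcripts moved after the change from short days in each line. No group was kept in short days alongside, so effects of long days and of added plant age cannot be told apart. At day 3, 1980 probe sets were called in FRI, 2487 in FRI flc-3 and 3485 in flc-3. The counts were 4305, 4594 and 6354 at day 5, and 3870, 6112 and 6883 at day 7. GI, a clock gene of the photoperiod pathway, fell from 139.6 to 64.9 in FRI, from 148.3 to 66.5 in FRI flc-3 and from 152.9 to 60.6 in flc-3 by day 3. Time of day did not enter the comparisons. For this clock gene a shift in daily timing and a change of level thus cannot be told apart. The floral integrators were called as a list by day 3 in FRI flc-3 (adjusted p = 0.0032, 2 of 3 members higher) and in flc-3 (adjusted p = 3.8e-04, 3 of 3). In FRI the list passed at day 5 with 3 of 3 members higher (adjusted p = 0.031), but not with an estimated correlation (adjusted p = 0.057), in a fit to only the arrays compared (adjusted p = 0.11) or at an offset of 16 (adjusted p = 0.0501). Flavonoid genes were lower as a list from day 3 in flc-3 (adjusted p = 0.0028) and from day 5 in FRI flc-3 (adjusted p = 0.0065), with 3 of 3 members each. Cold and dehydration genes were lower in 3 of 3 members by day 3 in each line, with list adjusted p of 4.4e-06, 2.5e-05 and 4.5e-05. For FRI flc-3 at day 3, a fit to only its 6 arrays gave 1431 calls.

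**Figure D4:**
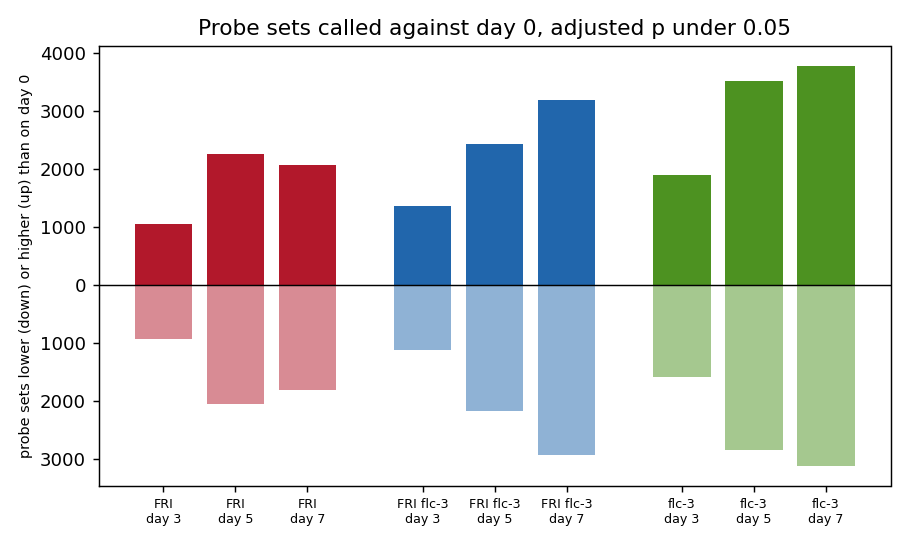
Number of probe sets called higher (upward) or lower (downward) than at day 0 in each line and on each day, of 14912 tested. The calls at day 7 numbered 3870 in FRI, 6112 in FRI flc-3 and 6883 in flc-3. At days 5 and 7 the balance of higher and lower calls turned over with a common 75th percentile, at day 5 from 2262 and 2043 to 2061 and 2245 in FRI.

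In FRI at day 7, the tested floral integrators rose and the tested cold-response genes fell relative to day 0. THI2.1 rose from 12.3 ± 5.6 to 228.3 ± 2.7 (SD, n = 3), a log2 change of 4.14 ± 0.20 (SE). AT2G25450 (GSL-OH), an enzyme of aliphatic glucosinolate synthesis, fell from 598.2 to 32.3, a log2 change of -4.15 ± 0.28. There were 2070 probe sets higher and 1800 lower, and 350 changed at least 2-fold. With a common 75th percentile 1748 were higher and 2040 lower, so which direction prevailed depends on the scaling. The 3 arrays of each day did not overlap for the loci named next, as chance gives for 10% of loci in 3 against 3 arrays.

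AT5G55450 rose by 3.23 ± 0.11, AT4G24110 by 2.60, the jacalin-related lectin JAL23 by 2.22, AT3G28500 by 2.19, AT1G10980 by 2.16, AT1G54020 by 2.12 and AT1G26680 by 2.06. AT1G56300 changed by -3.96 ± 0.20, AT1G70820 by -3.52, MSRB5, a methionine sulfoxide reductase, by -2.89, AT1G47400 by -2.85, AT2G47890 by -2.80, AT2G30540 by -2.68 and AT1G64370 by -2.62. Adjusted p for the 16 loci ran from 1.1e-21 to 3.2e-05. All kept their call at an offset of 16, 6 with changes smaller by over 1.5 times, such as AT1G26680 at 1.00 and AT2G47890 at -1.18. The unnamed probe sets 260355_at and 249606_at rose by 3.03 and 2.75, and 259161_at and 261574_at changed by -3.74 and -3.44.

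Of the floral integrators 3 of 3 rose, 3 adjusted over the list alone, with AGL42 at 1.51 ± 0.13 (0.94 at an offset of 16), FD at 0.67 ± 0.15 and AGL24 at 0.33 ± 0.10 (list adjusted p = 0.0036, held with an estimated correlation). The call of AGL24 was lost without replicate 1 of FRI at day 0 (log2 change 0.25, adjusted p = 0.10). UFO had a change of 0.16 ± 0.40 and SMZ of -0.42 ± 0.20, and neither passed (adjusted p = 0.82 and 0.14). COR15A, COR47 and LTI30 changed by -1.84, -1.59 and -1.88, LTI30 by -1.20 at an offset of 16 (3 of 3 lower, 3 adjusted over the list alone, list adjusted p = 3.7e-05). The flavonoid genes DFR, UF3GT and AT4G14090 had changes of 0.03, -0.11 and -0.01 with adjusted p of 0.80, 0.53 and 0.92 (list adjusted p = 0.89). Photosynthetic leaf genes were lower in 4 of 4 members with a median of -0.33 (list adjusted p = 0.0020). With an estimated correlation the list missed the threshold (adjusted p = 0.0501). RCA, the rubisco activase, changed by -0.55 ± 0.07 and PRK, the phosphoribulokinase, by -0.29 ± 0.08. LHCB4.1 changed by -0.29 and lost its call without replicate 2 or 3 of FRI at day 0 or at day 7 (adjusted p = 0.052, 0.11, 0.073 and 0.15). AT1G69570 (CDF5), a DOF factor of the photoperiod pathway, rose by 1.58 ± 0.22 (0.87 at an offset of 16) and GI changed by -1.10 ± 0.11. GID1B, a gibberellin receptor, rose by 1.12 ± 0.17, with a list adjusted p of 0.13.

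In FRI flc-3 at day 7, the floral integrators AGL42 and FD rose while the tested anthocyanin and cold-response genes fell. THI2.1 rose from 17.3 ± 4.6 to 786.6 ± 28.8 (SD, n = 3), a log2 change of 5.41 ± 0.20 (SE). BCAT4, which starts methionine chain elongation in glucosinolate synthesis, fell from 910.7 ± 50.6 to 11.3 ± 2.7, a change of -6.17 ± 0.10. There were 6112 calls, 3179 higher and 2933 lower, of which 1053 changed at least 2-fold. A common 75th percentile gave 2682 higher and 3448 lower, so which direction prevailed depends on the scaling.

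AT5G44630 rose by 5.47 ± 0.43, AT4G19430 by 5.16, AT1G54020 by 4.66, WSD1 by 4.13 ± 0.24, AT3G16330 by 3.96, AT4G14980 by 3.92 and AT3G28500 by 3.68. AT5G59330 changed by -6.56 ± 0.11, AT2G25450 by -6.40, AT1G56300 by -4.85, AT3G45160 by -4.72, PYK10 by -4.69 ± 0.09, AT5G61660 by -4.63 and AT1G70820 by -3.71. PYK10 went from 635.2 to 23.5. Adjusted p for the 16 loci ran from 3.2e-32 to 9.8e-10, and their arrays did not overlap between the days. All kept their call at an offset of 16, 4 with changes smaller by over 1.5 times, such as AT4G14980 at 1.71 and AT3G16330 at 2.00. The unnamed probe sets 247553_at and 259372_at rose by 6.27 and 6.01, and 249866_at and 261913_at changed by -6.20 and -5.23.

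AGL42 rose by 3.00 ± 0.13 and FD by 1.54 ± 0.15, while AGL24 had a change of -0.07 with adjusted p = 0.62 (2 of 3 members higher, 2 adjusted over the list alone, list adjusted p = 0.015). SMZ changed by -1.56 ± 0.20 (-0.76 at an offset of 16). UFO had a change of 2.06 ± 0.40 between signals of 2.52 and 15.8, both below the 40th percentile of every array, and of 0.77 at an offset of 16 (adjusted p = 1.0e-05). Flavonoid genes fell in 3 of 3 members, 3 adjusted over the list alone, with a median of -1.93 (list adjusted p = 7.1e-06). DFR went from 353.0 to 91.3, a change of -1.93 ± 0.07. Cold and dehydration genes fell in 3 of 3 members, 3 adjusted over the list alone, with COR15A at -3.67 ± 0.20 (list adjusted p = 8.9e-04). These 3 lists held with an estimated correlation. Photosynthetic leaf genes were lower in 4 of 4 members with a median of -0.45 (list adjusted p = 0.0064, and adjusted p = 0.088 with an estimated correlation). AUR1 and AUR2, Aurora kinases of mitosis, rose by 0.45 and 0.42 while PRL changed by -0.40, and the cell cycle list did not pass (adjusted p = 0.53). GI changed by -1.38 and AT1G69570 rose from 11.5 to 24.9 (adjusted p = 1.3e-04), by 0.59 at an offset of 16.

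In flc-3 at day 7, the floral integrators AGL42 and FD rose, and the tested genes of anthocyanin synthesis, the cold response and photosynthesis fell. AT5G44630, a locus of the terpene synthase family, rose from 3.92 to 261.6, a log2 change of 5.86 ± 0.43 (SE, 3 against 3 arrays). BCAT4 fell from 1107 ± 41.2 to 15.3 ± 0.65 (SD, n = 3), a change of -6.03 ± 0.10. There were 6883 calls, 3772 higher and 3111 lower, of which 1173 changed at least 2-fold. With a common 75th percentile 3028 were higher and 3767 lower, so the balance of directions depends on the scaling.

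THI2.1 rose by 4.92 ± 0.20, AT4G00870 by 4.86, UGT84A1 by 4.62, AT3G28500 by 4.50, AT1G54020 by 4.44, WSD1 by 4.32 ± 0.24 and AT5G22430 by 3.87. AT4G00870 and UGT84A1 started at signals of 0.79 and 1.08, below the 40th percentile of every array. The 16 loci kept their call at an offset of 16, 5 with changes smaller by over 1.5 times, such as AT4G00870 at 2.33 and UGT84A1 at 2.24. AT2G25450 changed by -7.27 ± 0.28, AT5G59330 by -5.18, AT3G45160 by -4.70, PYK10 by -4.21 ± 0.09, AT5G61660 by -4.14, AT1G56300 by -3.92 and COR15A by -3.77 (-2.50 at an offset of 16). Adjusted p for the 16 loci ran from 6.7e-32 to 9.2e-08, and their arrays did not overlap between the days. The unnamed probe sets 247553_at and 267460_at rose by 5.71 and 5.49, and 249866_at and 262717_s_at changed by -6.44 and -4.96.

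AGL42 rose by 2.92 ± 0.13 and FD by 1.41 ± 0.15, while AGL24 had a change of 0.19 with adjusted p = 0.11 (2 of 3 members higher, 2 adjusted over the list alone, list adjusted p = 0.0094). UFO rose by 3.16 ± 0.40 from a dim 1.34 to 24.7, and by 1.23 at an offset of 16, and SMZ changed by -1.84 ± 0.20 (-0.92 at that offset). DFR, UF3GT and AT4G14090 changed by -2.27, -1.49 and -1.32 (3 of 3 lower, 3 adjusted over the list alone, list adjusted p = 2.9e-05). Cold and dehydration genes fell in 3 of 3 members, 3 adjusted over the list alone (list adjusted p = 2.9e-04). Photosynthetic leaf genes fell in 4 of 4 members, 4 adjusted over the list alone, with RCA at -0.75 and LHCB4.1 at -0.77 (list adjusted p = 0.0013). These 4 lists held with an estimated correlation. AUR1 rose by 0.59 and AUR2 by 0.31, and the cell cycle list had an adjusted p of 0.41. AT1G69570 rose by 0.96 (0.55 at an offset of 16), GI changed by -1.25 and GID1B rose by 0.71.

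The difference between the day 7 responses of FRI flc-3 and FRI asked whether the response depended on FLC. AGL42 and FD rose more in FRI flc-3, and BCAT4 fell more. The tested anthocyanin genes fell in FRI flc-3 and were not called in FRI. BCAT4 ended at 272.4 in FRI and at 11.3 in FRI flc-3, a difference of responses of -4.13 ± 0.14 (log2, SE). WSD1 ended at 6.45 ± 2.5 in FRI and at 267.5 ± 42.3 in FRI flc-3 (SD, n = 3), a difference of 4.79 ± 0.34. The contrast called 1893 probe sets, 937 positive and 956 negative, and 583 differed at least 2-fold.

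The positive differences included AT5G44630 at 4.87 ± 0.61, AT4G19430 at 3.86 ± 0.26, AT4G00870 at 3.46 ± 0.55 and AT5G02230 at 3.30 ± 0.78. AT4G00870 and AT5G02230 ended at 0.56 and 6.53 in FRI and at 23.2 and 40.8 in FRI flc-3. At an offset of 16 their differences were 1.23 and 1.54, with adjusted p of 3.1e-08 and 2.1e-05. The negative ones included AT5G59330 at -5.62 ± 0.15, AT3G45160 at -4.80 ± 0.14, AT5G61660 at -3.60 and AT5G05790 at -3.50 (-1.78 at an offset of 16). Adjusted p for the 10 named loci ran from 2.9e-24 to 0.0029. The unnamed probe sets 259372_at and 247553_at stood at 5.70 and 5.52, and 263285_at and 249866_at at -4.55 and -4.15. Flavonoid genes had negative differences in 3 of 3 members, 3 adjusted over the list alone, with DFR at -1.96, UF3GT at -1.88 and AT4G14090 at -1.55 (list adjusted p = 1.4e-10, held with an estimated correlation). AGL42 and FD had positive differences of 1.49 ± 0.18 and 0.87 ± 0.21, 2 of 3 integrators. Adjusted over the list alone 3 passed, but AGL24 went the other way. It rose by 0.33 in FRI and was not called in FRI flc-3. The list itself did not pass with camera (adjusted p = 0.11) and did so at an offset of 16 (adjusted p = 0.047). COR15A stood at -1.82 ± 0.28 and THI2.1 at 1.27 ± 0.28. SMZ stood at -1.14 ± 0.29, and after quantile normalization at -0.87 with adjusted p = 0.0503. SMZ was dim in 3 of the 4 groups and stood at -0.50 at an offset of 16, and COR15A at -1.11. UFO stood at 1.90 ± 0.57 with all 4 groups dim (0.73 at an offset of 16), and its call was lost in a fit to only the 12 arrays compared (adjusted p = 0.081) and without FRI day 0 replicate 1, FRI day 7 replicate 3 or FRI flc-3 day 7 replicate 2 (adjusted p = 0.0505, 0.076 and 0.067). GI and AT1G69570 had differences of -0.28 and -0.48 with adjusted p of 0.29 and 0.38.

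The difference between the day 7 responses of FRI flc-3 and flc-3 asked whether the FRI allele altered the response where FLC was mutant. It called 424 probe sets, 205 positive and 219 negative, and 28 differed at least 2-fold. The positive named loci were MSRB5 at 1.90 ± 0.31, AT4G19430 at 1.42 ± 0.26, AT3G44370 at 1.22 ± 0.34, AT3G28220 at 1.07 ± 0.20 and AT5G22620 at 1.05 ± 0.25. The negative ones were AT5G41400 at -1.80 ± 0.26, AT1G48660 at -1.76 ± 0.38, AT5G59330 at -1.38 ± 0.15, AT1G71180 at -1.30 ± 0.24 and AT1G67860 at -1.24 ± 0.20. At an offset of 16, AT5G41400 and AT1G48660 stood at -0.56 and -0.56 with adjusted p of 0.092 and 0.069, so both calls ended. There AT5G59330, AT3G44370 and AT4G19430 stood at -0.62, 0.69 and 0.94 and kept their call. Adjusted p of the 10 ran from 1.1e-06 to 0.043. The unnamed probe sets 245276_at and 264007_at stood at 1.71 and 1.16, and 254098_at and 262445_at at -1.77 and -1.31. AGL42, FD and SMZ had differences of 0.09, 0.13 and 0.28 with adjusted p of 0.86, 0.81 and 0.67, and UFO had an adjusted p of 0.32. COR47 stood at 0.67 ± 0.18, and its list did not pass with camera (adjusted p = 0.11) and did so in a fit to only the arrays compared (adjusted p = 0.025).

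The count of 424 depends on the fit and on single arrays. A fit to only the 12 arrays of the groups compared gave 30 calls, and leaving out replicate 3 of FRI flc-3 at day 0 gave 207. In the former fit AT4G19430, AT3G44370, AT5G22620, AT1G48660 and AT1G67860 missed the threshold (adjusted p = 0.053, 0.11, 0.090, 0.12 and 0.053). With a common 75th percentile there were 435 calls, 256 positive and 179 negative.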

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

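The tests of the chromosome 4 window by direction and by neighbouring loci, and those of the scaling, the spread and a later transition in FRI, were chosen after the result had been seen. The splits of the arrays were planned.

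The day 7 response of FRI flc-3 differed from that of FRI for 1893 probe sets by a test of the difference itself. The named loci AT5G44630 (4.87), WSD1 (4.79), AT4G19430 (3.86), AT4G00870 (3.46), AT5G02230 (3.30), AT5G59330 (-5.62), AT3G45160 (-4.80), BCAT4 (-4.13), AT5G61660 (-3.60) and AT5G05790 (-3.50) passed that test, with log2 differences in brackets. So did COR15A (-1.82), DFR (-1.96), AT4G14090 (UGT75C1, -1.55), UF3GT (-1.88), AGL42 (1.49), FD (0.87), SMZ (-1.14) and THI2.1 (1.27). The flavonoid and anthocyanin list had a median difference of -1.88. UFO (1.90) passed, but not without FRI day 0 replicate 1 (adjusted p = 0.0505), FRI day 7 replicate 3 (0.076) or FRI flc-3 day 7 replicate 2 (0.067), nor in a fit to only the arrays compared (0.081). AUR2 (0.39) passed, but not without FRI day 0 replicate 1 (0.12), FRI flc-3 day 0 replicate 1 (0.077) or FRI flc-3 day 7 replicate 3 (0.084), nor in a fit to only the arrays compared (0.11). Of 100 splits of the arrays between the lines within each day, 3 gave as many calls, the real one included, and the highest other split gave 2369. Those 3 were among the 6 splits that kept the day 7 arrays as labelled, and no split that mixed the day 7 arrays gave more than 28. The splits thus followed the day 7 arrays and do not decide whether the difference of responses came by chance.

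The day 7 response of FRI flc-3 differed from that of flc-3 for 424 probe sets. The named loci were MSRB5 (1.90), AT4G19430 (1.42), AT3G44370 (1.22), AT3G28220 (1.07), AT5G22620 (1.05), AT5G41400 (-1.80), AT1G48660 (-1.76), AT5G59330 (-1.38), AT1G71180 (-1.30) and AT1G67860 (-1.24), again as log2 differences. COR47 (0.67) passed as well, with adjusted p = 0.034. It missed the threshold with no filter (adjusted p = 0.053), with eBayes without the trend (0.051) and without FRI flc-3 day 0 replicate 3 (0.078), FRI flc-3 day 7 replicate 2 (0.079) or 3 (0.074), flc-3 day 0 replicate 1 (0.057) or 2 (0.074), and flc-3 day 7 replicate 1 (0.058) or 3 (0.082). Of 100 splits only the real one gave as many calls, and the highest other gave 241. Of these splits 12 kept the day 7 arrays as labelled, too few for a share under 0.05, and the others gave at most 49.

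In FRI the response at day 7 was smaller than in FRI flc-3. Over 1173 probe sets chosen on flc-3, the median log2 response was 0.60 in FRI and 1.41 in FRI flc-3, and 89.8% were smaller in FRI. This choice favours FRI flc-3, which shares the mutant FLC with flc-3. Without such a choice, 350 probe sets called at day 7 changed at least 2-fold in FRI and 1053 in FRI flc-3. The authors' scaling is argued against, since a share of 0.963 of the calls of the difference was left with a common 75th percentile. The spread in FRI had a ratio of 0.955 to the spread in FRI flc-3. All groups shared the estimate of the spread in the fit, so a larger spread in FRI could not lower its calls alone. The ratio thus decides nothing here. For a later transition in FRI, 3 of 3 FRI arrays of day 7 were nearest to day 3 of FRI flc-3. The distances of the group means were 47.1, 31.0, 34.1 and 61.3 to days 0, 3, 5 and 7 of FRI flc-3. A response that was only weaker would also lie nearer an earlier day, so the distances do not decide. A weaker response without a delay was not tested, and it and a later transition both stay open.

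Calls between FRI flc-3 and flc-3 gathered at the top of chromosome 4. The window's 2 runs of 50 loci held 20 and 10 calls, and the fullest run outside it held 6. These runs recount the calls behind the odds ratio and show a local excess only. As 257 called loci lay outside the window, a further line difference spread over the genome stays open. Lost hybridization through sequence differences of linked Sf-2 DNA was taken to lower signals only, which was not checked on the probe sequences. On that premise it is argued against for the 8 members higher in FRI flc-3. There 1.48 would be met at the rate outside (one-sided exact binomial p = 1.3e-04), with neighbouring loci taken as independent. For the 22 lower members, against 1.72 at that rate (one-sided exact binomial p = 3.0e-18), lost hybridization and lower transcript levels of linked alleles cannot be told apart without the probe sequences. Other differences between the lines in this region stay open as untested.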

How the results depend on the processing

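The offset of 16 was chosen after the data had been seen, and all other alternatives were planned. Of 13 counts of calls, 13 stayed within 1.5 times the reported value under the other offsets, quantile normalization, the common 75th percentile, no filter, the filter at the 60th percentile, the replicate block, array weights and eBayes without the trend. In a fit to only the arrays compared, FRI flc-3 at day 3 had 1431 calls (1404 shared with the 2487) and the difference between FRI flc-3 and flc-3 had 30, and fewer arrays to estimate the spread enter that fit. Leaving out single arrays moved the latter between 207 (without FRI flc-3 day 0 replicate 3) and 498 (without FRI flc-3 day 7 replicate 1). It was also 216 without flc-3 day 7 replicate 3, 257 and 258 without FRI flc-3 day 7 replicates 2 and 3, and 278 without flc-3 day 0 replicate 2, and the cause was not tested. The other counts stayed within 1.5 times when any array was left out, for example 2925 to 3191 for FRI against FRI flc-3 and 1610 to 1930 for the difference between FRI flc-3 and FRI. No value reversed. The odds ratio of the chromosome 4 window ran from 9.65 to 16.4 over left-out arrays.

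Of 104 list tests, 5 lost their call with an estimated correlation, 4 of them for photosynthetic leaf genes, and fry, which asks another question, called 36 more. Among 193 values of named genes and list members, 184 kept their call in a fit to only the arrays compared, 187 without FRI day 0 replicate 2, and 188 or more under every other alternative that tested them all. The filter at the 60th percentile left 143 of them. AT3G44370 in the difference between FRI flc-3 and flc-3 had adjusted p between 0.034 and 0.11 over the alternatives. Its call ended with array weights (adjusted p = 0.063), with no filter (0.071) and after quantile normalization (0.05001). It also ended in a fit to only the arrays compared (0.11) and without any 1 of 10 arrays. These were FRI flc-3 day 0 replicates 1, 2 and 3, FRI flc-3 day 7 replicates 1 and 3, flc-3 day 0 replicates 2 and 3, and flc-3 day 7 replicates 1, 2 and 3. In the same contrast AT5G41400 and AT1G48660 stood at -0.56 and -0.56 at an offset of 16 with adjusted p of 0.092 and 0.069, and AT5G22620 at 0.90 without flc-3 day 0 replicate 3 with adjusted p = 0.060. Deviations of arrays of equal replicate number in different groups had a mean correlation of 0.0023 and a highest of 0.363, against -0.0011 and 0.148 for unequal numbers, and 13 of 36 arrays correlated best with their own number. The highest was between FRI flc-3 day 0 replicate 3 and flc-3 day 7 replicate 3, the arrays without which the count of 424 was lowest. The planned look at FLC, FRI and SOC1 was not run.

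With 3 arrays per day, the splits of a day response are too few for a share under 0.05, as 1 of 10 is the real one. The real counts and the highest other were 1980 and 1, 4305 and 1, and 3870 and 2 for FRI at days 3, 5 and 7. They were 2487 and 30, 4594 and 2, and 6112 and 9 for FRI flc-3, and 3485 and 1, 6354 and 1, and 6883 and 2 for flc-3. For the lines, only the real split of 100 gave as many calls (value 1 of 100 each). The real count and the highest other were 3160 and 1160 for FRI against FRI flc-3, and 632 and 81 for FRI flc-3 against flc-3. A random assignment of these arrays to the lines is thus argued against. A chance difference between the plants of the lines is not, since the labels do not state whether replicates came from separate pools. Signals under the 40th percentile limit what can be said of dim genes.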

Other observations

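The lists, the families and the search for probe sets that set a line apart were chosen after values had been seen. Of 17 tested genes of the core low-oxygen response, 13 rose and 1 fell at day 7 in FRI, 13 rose and 3 fell in FRI flc-3, and 14 rose and 2 fell in flc-3 (list adjusted p = 5.4e-11, 1.2e-07 and 1.6e-07, and 2.2e-06, 2.1e-05 and 2.1e-05 with an estimated correlation). AT4G24110 rose by 2.60, 2.98 and 2.96, AT4G27450 by 1.53, 2.01 and 2.00, and AT3G29970 by 1.33, 3.16 and 2.36. PDC2, a pyruvate decarboxylase, changed the other way, by -1.08, -1.23 and -1.32. Other members of the list were not tested, among them ADH1, PDC1, SUS1, SUS4, HRE1 and HRE2. The list result thus speaks for the tested members only. Without AT4G24110, which the text names elsewhere, the list was still called in FRI (adjusted p = 1.5e-09). With a common 75th percentile 12 rose in FRI.

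The 4 tested genes of aliphatic glucosinolate synthesis were BCAT4, AT2G25450 (GSL-OH), GSTU20 and AT2G31790. This list was chosen after BCAT4 and AT2G25450 had been seen to fall. In each line 4 of 4 members were lower at day 7, with medians of -1.45 in FRI, -3.82 in FRI flc-3 and -3.67 in flc-3 (list adjusted p = 3.5e-09, 9.2e-08 and 2.5e-08). All 4 were higher in FRI than in FRI flc-3, with a median of 0.77 (list adjusted p = 9.9e-08). Without BCAT4 and AT2G25450 that median was 0.30 (list adjusted p = 0.0030). Without BCAT4 and AT2G25450, the 2 members left had medians of -0.69, -0.98 and -1.22 at day 7 (list adjusted p = 4.6e-04, 0.0030 and 6.6e-04). Of the BGLU family of beta-glucosidases, 7 of 10 members by symbol were higher in FRI than in FRI flc-3, with a median of 0.25 (adjusted p = 0.0013, and 0.016 with an estimated correlation). Of the ATG family, genes of autophagy, 4, 6 and 7 of 7 members rose at day 7 in FRI, FRI flc-3 and flc-3 (adjusted p = 0.0050, 0.0061 and 0.0046), and adjusted p = 0.17 with an estimated correlation in each line. With a common 75th percentile 4, 5 and 6 of the 7 rose, and 7 of the 10 BGLU members were still higher in FRI.

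Some probe sets set a line apart from the others, with all 12 arrays beyond all 24 others. Random exchange of the arrays gives this for 1.6e-07% of probe sets. That share takes the arrays of a line as independent, and it does not measure chance differences between the plants of the lines. In FRI there were 5: 250476_at (782.7 ± 104.2 against 34.2 ± 14.3, SD) and ARPN (722.0 against 512.7) were higher, and AT2G45180 (307.3 against 650.5), 253579_at and 264339_at were lower. In FRI flc-3 there were 3: AT5G24240 (63.1 ± 9.7 against 2.26 ± 1.3) and 264324_at (163.6 against 46.0) were higher and 253995_at (47.3 against 127.2) was lower. In flc-3 there were 5, all higher: AT4G00520, AT4G01460, AT4G01860, 255589_s_at and 255676_at. The named loci among them lie in the chromosome 4 window. There, lost hybridization in the lines with Sf-2 DNA and lower transcript levels cannot be told apart.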
